A study of Mus musculus with 12 samples.

How the data were processed

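Gene expression was measured by RNA sequencing in livers of male C57BL/6 mice, in 12 libraries that fall into 4 groups of 3. Per the labels' protocols, mice received either chow with normal water or a Western diet with sugar water from 6 weeks of age. After 12 weeks they were given, by tail vein, AAV8 particles with the hepatocyte-directed TBG promoter that carried either no insert (null) or a sequence to silence Aatf (siAATF), and livers were taken 12 weeks later. RNA was extracted with a column kit that takes DNA and RNA from the same tissue, and libraries were made with a SMART-Seq kit, per the labels' protocols. The labels number the replicates 1 to 3 in each group and do not state that each number is a separate mouse, so the p-values measure only the spread between these samples.

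The deposited table holds counts of reads per gene, which are whole numbers. Reads were aligned with STAR 2.7.11 and counted with featureCounts 2.0.1 in R 4.3.2, and DESeq2 1.42.0 was used for the comparisons, on the mouse build GRCm39, per the submitters' processing notes. The strand setting and the treatment of reads that fall on several genes are not given in the sources used here. The table itself shows part of this. Each gene's length equals its whole span from start to end, so introns were counted with exons. All 10408 genes that lie inside another gene are listed at 0, whether the outer gene is on the other strand only (5778 genes) or on the same strand (4630 genes). Reads that fall on 2 overlapping genes were therefore not assigned to the inner gene, and strand did not separate the genes. Among the members of the fixed gene lists, 33 lie inside another gene and are listed at 0, Timp1, Il1b, Il6 and Cxcl10 among them, so they are not analysed here. Of the 11934 genes tested, 46.8% overlap a neighbour in part, and for these part of the reads is missing. Reads of near-identical copies (the Mup genes, the Serpina1 genes, the glutathione S-transferases) could have been split or dropped in counting, so their levels are uncertain.

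The table lists 50499 genes, of which 28210 are at 0 in all 12 libraries. The total count per library ran from 1646853 to 13469819. The 18S ribosomal RNA gene Rn18s-rs5 took between 0.871% and 50.8% of a library's counts, so the depth left for other genes differed from the total. The floor of 3 counts corresponded to between 0.185 and 1.69 counts scaled by library size (CPM). Reads carry no molecular identifiers, so intervals and floors cover counting error only. Pairs of replicates differed by far more than sampling noise (chi-square per degree of freedom at least 11.0 in every pair, the 18S gene included). No library was therefore counted as a second sequencing run of another. This does not show that the libraries came from separate mice.

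From the counts as deposited, CPM values were computed with TMM library sizes. Genes were kept with edgeR's filterByExpr by group. The main test was edgeR's quasi-likelihood test (edgeR 4.0.16, R 4.3.3, robust dispersion estimates) in 1 fit of all 12 libraries with a mean per group, which leaves 8 residual degrees of freedom, with Benjamini-Hochberg adjustment over the genes of each comparison and a threshold of 0.05. The series names 3 comparisons: Western null against chow null, Western siAATF against Western null, and chow siAATF against chow null. Western siAATF against chow siAATF and the interaction of diet and vector follow from the 2 by 2 design. Log2 fold changes are given with their standard error, and levels as mean CPM ± SD over 3 libraries. Fold changes against a group with 0 counts are given as lower bounds from a floor of 3 counts over the group, and those against a group with 1 to 3 counts as ratios of summed counts with a 95% counting interval. Gene lists (36) were written before the data were examined, as were the designs, the tests and the first set of alternatives. Lists with at least 5 measured members (33) were tested with limma 3.58.1 camera on log2 CPM (prior count 2) with a preset inter-gene correlation of 0.01, adjusted over lists and the 5 comparisons together, and again with an estimated correlation and with fry.

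Genes are named by a rule fixed before the data were examined. It takes, for each comparison the series names, Aatf, the 6 higher and 6 lower genes with the largest fold change among those past the threshold, with a mean of at least 5 CPM in the higher group, no overlap between the 3 and 3 libraries and no predicted-model symbol; up to 4 members per list by adjusted p; 18 genes well known in steatohepatitis whatever their value; 5 interaction genes by adjusted p; and, where no gene passes, 5 higher and 5 lower genes by unadjusted p. A gene can be named under several parts. 1 gene that the rule names is not reported here. Exceptions are marked where they occur.

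The main edgeR test and camera with the preset correlation were tried on simulated counts with 200 changed genes. These counts were drawn from each gene's mean over all 12 libraries and from the real library sizes and dispersions. In Western siAATF against Western null, 48 of 64 genes changed 4-fold were called, and 5 of 65 changed 2-fold, among 11313 genes tested. In chow siAATF against chow null the same step called 50 of 60 and 8 of 66, among 11208 genes tested. For the interaction, 21 of 64 genes changed 4-fold were called, among 11497 genes tested. In the 3 comparisons the series names, 2 of 58, 2 of 56 and 2 of 62 called genes had not been changed. In Western siAATF against chow siAATF it was 4 of 67, and for the interaction 3 of 24. Alternatives were DESeq2 size factors, TMMwsp, DESeq2 1.42.0, limma-voom with quality weights, no low-count filter, a stricter filter (at least 1 CPM in 3 libraries), a fit of the compared groups alone, a replicate block, glmTreat at a fold of 1.5, an adjusted p under 0.1, and each library left out. Alternatives added after the data were seen were a correction for gene-span length, removal of structural RNA, genes without an overlapping neighbour, thinning to equal depth, and the omission of the 4 libraries with over 25% 18S RNA. That omission drops chow null replicates 1 and 2, chow siAATF replicate 1 and Western siAATF replicate 2. In chow null only replicate 3 is then left. The reference annotation at hand is of another build, so its coordinates were not used here.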

Results

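The study measured liver transcriptomes of mice in a diet model of metabolic dysfunction-associated steatohepatitis (MASH), with a vector meant to silence Aatf in hepatocytes. Aatf encodes a nucleolar and transcriptional regulator. There were 12 libraries in 4 groups of 3: chow with the null vector (chow null), chow with the silencing vector (chow siAATF), Western diet with sugar water and the null vector (Western null), and the same diet with the silencing vector (Western siAATF). Chow null libraries held 2245022 to 9512246 counts, chow siAATF 4200079 to 13469819, Western null 1646853 to 8917363, and Western siAATF 1989409 to 7614183. On the first principal component of log2 CPM, which held 34.1% of the variance, Western null libraries lay between 44.4 and 63.9 and chow null libraries between -46.1 and -39.0. Both siAATF groups lay between them, chow siAATF from -38.5 to -23.3 and Western siAATF from -3.93 to 29.7. The 18S ribosomal RNA gene took 25.2%, 30.4% and 4.28% of the counts in chow null, 41.4%, 1.54% and 4.25% in chow siAATF, 5.80%, 14.4% and 2.84% in Western null, and 19.8%, 50.8% and 0.871% in Western siAATF.

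Aatf, the gene the vector targets (GRCm39 chromosome 11, 84313682 to 84404433, minus strand), was counted in every library. In chow null its replicates stood at 36.8, 26.5 and 31.6 CPM (mean 31.6 ± 5.13 SD, n = 3), and in chow siAATF at 39.2, 24.6 and 40.5 CPM (34.8 ± 8.86). In Western null they stood at 27.6, 21.1 and 30.0 CPM (26.3 ± 4.60), and in Western siAATF at 27.0, 27.5 and 28.2 CPM (27.5 ± 0.599). Aatf was not lower in the libraries labelled siAATF. The log2 fold change was 0.06 ± 0.25 on the Western diet (edgeR quasi-likelihood test, Benjamini-Hochberg adjusted p = 0.953) and 0.11 ± 0.24 on chow (same test, adjusted p = 1). The 95% intervals ran from -0.47 to 0.59 and from -0.40 to 0.63, so a fall of the counted Aatf signal to 72.2% or less of the null level on the Western diet, or to 75.6% or less on chow, lay outside them. The Western estimate turned to -0.02 with limma-voom, -0.09 without Western null replicate 2 and -0.06 after thinning to equal depth, none of which passed. The count takes in the introns as well as the exons of Aatf, and it is of liver tissue, not of hepatocytes alone. Below, the vector groups are therefore libraries labelled siAATF, and every direction given for the vector rests on that label and not on a measured fall of Aatf.

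**Figure D1:**
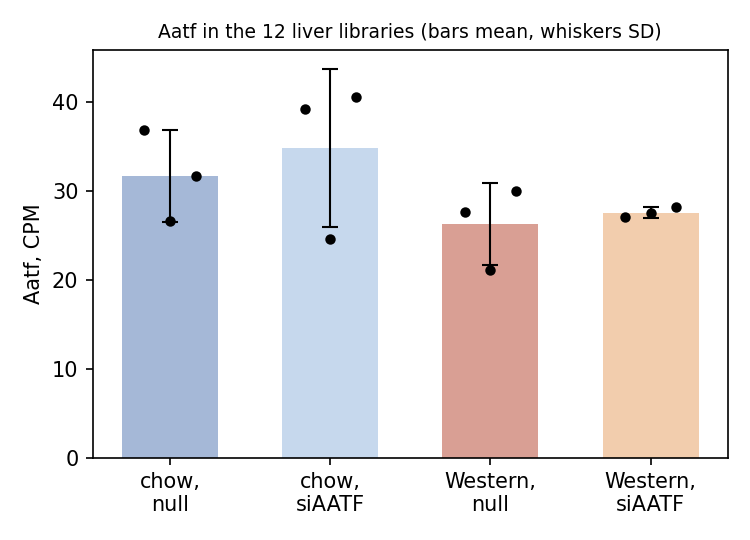
Aatf level in CPM (y axis, from 0) in the 4 groups (x axis); points are the 12 libraries, bars the group means and whiskers the SD. The Western siAATF libraries, at 27.0 to 28.2 CPM, sit within the range of the Western null libraries.

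The first comparison asks what the Western diet did to the liver in mice given the null vector. Most genes on the lists of lipid-laden macrophages and of scar matrix rose, some genes of lipid storage rose, and most genes on the lists of cholesterol synthesis and of the male liver programme fell. Of these lists only that of the macrophages kept its call with an estimated correlation. By fry each of them passed, with the largest adjusted p for cholesterol synthesis (0.0197 by fry). Gpnmb, a glycoprotein of lipid-associated macrophages, rose from 0.181 ± 0.243 to 47.6 ± 4.49 CPM (log2 fold change 7.59 ± 0.55). Apoa4, a lipoprotein component induced in fatty liver, rose from 140 ± 54.8 to 8474 ± 1699 CPM (5.92 ± 0.38). Hsd3b5, a steroid dehydrogenase of the male liver, fell from 229 ± 30.5 to 0.718 ± 0.883 CPM (-8.40 ± 0.56). Of 11934 genes tested, 769 were higher and 808 lower in Western null (edgeR quasi-likelihood test, Benjamini-Hochberg adjusted p under 0.05).

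Of 17 measured lipid-associated macrophage markers, 13 rose and 0 fell; adjusted over the list alone, 14 rose and 1 fell. Besides Gpnmb these included Cd63 (log2 4.50 ± 0.34) and Anxa5 (2.58 ± 0.26). Mmp12, the macrophage elastase, had 409 counts in the Western null libraries against 1 in chow null, a ratio of 559 with a 95% counting interval of 99.8 to 22143. Trem2, a lipid receptor of these cells, had 286 counts against 3, a ratio of 130 (44.2 to 636). Spp1, which encodes osteopontin, rose by 3.77 ± 0.47. The list as a whole was higher by camera (adjusted p = 3.52e-15), and it was the only list called here whose call held with an estimated correlation (adjusted p = 0.00156 with an estimated correlation). Of the 17, Mmp12 is also in the matrix list, Lpl in the lipid droplet list, and Ctsb and Ctsd in the lysosome list.

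Of 27 measured genes of extracellular matrix and fibrosis, 21 rose and 0 fell (25 and 0 adjusted over the list alone). Col1a1, the main fibrillar collagen, rose from 8.83 ± 8.06 to 271 ± 75.2 CPM (5.21 ± 0.91), Col6a3 by 3.20 ± 0.37, Col5a2 by 3.24 ± 0.46 and the fibrillin gene Fbn1 by 2.13 ± 0.27. The camera call of the list (adjusted p = 3.19e-17) was not kept with an estimated correlation (adjusted p = 0.0884 with an estimated correlation). Of 13 stellate cell and myofibroblast markers, 4 rose, among them Vim (1.99 ± 0.34), Pdgfrb (1.66 ± 0.34) and Cygb (1.65 ± 0.34), and 1 fell (7 and 1 adjusted over the list alone; adjusted p = 0.203 with an estimated correlation). Of 15 genes of antigen presentation, 8 rose (11 adjusted over the list alone; adjusted p = 0.227 with an estimated correlation), led by the class II genes H2-Eb1 (3.08 ± 0.34), H2-Ab1 (2.46 ± 0.41), H2-Aa (2.41 ± 0.39) and Cd74 (2.35 ± 0.40). Kupffer and pan-macrophage markers moved apart: 6 of 15 rose, including Cd68 (2.15 ± 0.42), C1qb (1.69 ± 0.41) and Mpeg1 (1.66 ± 0.36), and 2 fell, including the scavenger receptor Cd163 (-2.29 ± 0.58; 7 and 2 adjusted over the list alone; adjusted p = 0.524 with an estimated correlation). Markers of other cell types moved with them. Of 15 liver endothelial markers 4 rose, Lyve1 (2.15 ± 0.43), Vwf (1.69 ± 0.37), Pecam1 (1.16 ± 0.33) and Stab1 (0.93 ± 0.28), and 0 fell by edgeR's test (5 and 0 adjusted over the list alone; adjusted p = 0.288 with an estimated correlation). Of 9 cholangiocyte and ductular markers 3 rose, Epcam (3.62 ± 1.11), Tspan8 (3.22 ± 0.72) and Prom1 (2.46 ± 0.60; 3 higher and 1 lower adjusted over the list alone), and the list was not called. Of 24 hepatocyte secreted proteins 5 fell, among them Serpina1c (-1.76 ± 0.25), Fetub (-1.10 ± 0.26) and Plg (-0.99 ± 0.25), and 0 rose by edgeR's test (5 lower adjusted over the list alone; adjusted p = 0.295 with an estimated correlation).

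Among 18 genes of lipid droplets and lipid uptake, 6 rose (12 adjusted over the list alone; adjusted p = 0.227 with an estimated correlation). The fatty acid transporter Cd36 rose by 3.85 ± 0.55, the droplet proteins Cidec and Plin4 by 4.47 ± 1.08 and 3.45 ± 0.66, and the fatty acid binding protein Fabp4 by 2.83 ± 0.51. De novo lipogenesis had 5 of 22 genes higher (5 adjusted over the list alone; adjusted p = 0.504 with an estimated correlation): Thrsp rose by 4.17 ± 0.55, Scd2 by 2.34 ± 0.43, the desaturase gene Scd1 by 1.91 ± 0.38 and Tkfc by 1.03 ± 0.26. Fasn, the fatty acid synthase gene, did not pass (0.61 ± 0.38), nor did its regulator Srebf1 (0.84 ± 0.35). Of 24 genes of cholesterol synthesis and uptake, 15 fell and 0 rose (17 and 0 adjusted over the list alone; adjusted p = 0.288 with an estimated correlation). Idi1 fell by 4.58 ± 0.66, the squalene epoxidase gene Sqle by 3.63 ± 0.65, Cyp51 by 3.12 ± 0.56 and Nsdhl by 2.84 ± 0.51. Cyp7a1, which encodes the rate-limiting enzyme of the classic bile acid pathway, rose by 2.03 ± 0.38, and Cyp7b1 of the alternative pathway fell by 4.12 ± 0.54.

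Male-biased liver genes fell in 19 of 23 cases (20 adjusted over the list alone), with a camera call (adjusted p = 4.11e-15) that was not kept with an estimated correlation (adjusted p = 0.0884 with an estimated correlation). Besides Hsd3b5, Serpina1e fell from 6066 ± 1383 to 36.6 ± 5.54 CPM and Susd4 by 3.73 ± 0.50. Among the major urinary protein genes, whose near-identical copies make the counts uncertain, Mup11 fell by 8.03 ± 1.57, Mup1 had 385 counts in chow null against 2 in Western null (ratio 141, 38.7 to 1167) and Mup12 had 348 against 2 (ratio 127, 35.0 to 1055). Pitx3 had 413 counts against 1 (ratio 302, 53.9 to 11958); its span overlaps that of Elovl3, a male-biased gene on the other strand that fell by 4.40 ± 0.67 (named outside the rule, for the overlap), and the unstranded counts do not separate them at the overlap. Clock genes moved in both directions, with 9 of 19 higher and 4 lower (9 and 4 adjusted over the list alone; adjusted p = 0.378 with an estimated correlation): Usp2 rose by 4.88 ± 0.47, Wee1 by 4.58 ± 0.55 and Per3 by 2.58 ± 0.40, and Arntl fell by 3.11 ± 0.44. The labels give no hour of tissue collection.

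The remaining genes with the largest changes were Ly6d, a membrane protein (7.21 ± 0.61), Fam83a (283 counts against 2, ratio 193, 53.1 to 1605) and the glutathione S-transferase gene Gsta1, with 82 counts in Western null and 0 in chow null, at least 37.4-fold higher. The cell cycle inhibitor Cdkn1a rose by 2.54 ± 0.61. Cyp2e1 (-0.31 ± 0.25), Fgf21 (1.43 ± 1.02) and Ddit3 (-0.07 ± 0.41) did not pass. Timp1 is listed at 0 in every library because its gene lies inside another, and Tnf and Ccl2 fell under the low-count filter. Of 121 named genes called for the diet, 64 stayed called in every alternative in which they were tested, and none turned direction. This check left out glmTreat and the adjusted p under 0.1. The count of 1577 changed genes moved with the libraries used, to 658 without chow null replicate 3 and 955 without chow null replicate 1. Without Western null replicates 1, 2 and 3 it became 822, 771 and 990. Omitting the 4 libraries with over 25% 18S RNA leaves only chow null replicate 3 in its group, so its count is not set beside these. Longer genes had lower fold changes in this comparison (Spearman -0.291 across genes, which are not independent replicates); after a correction for gene span 702 genes were higher and 619 lower.

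**Figure D2:**
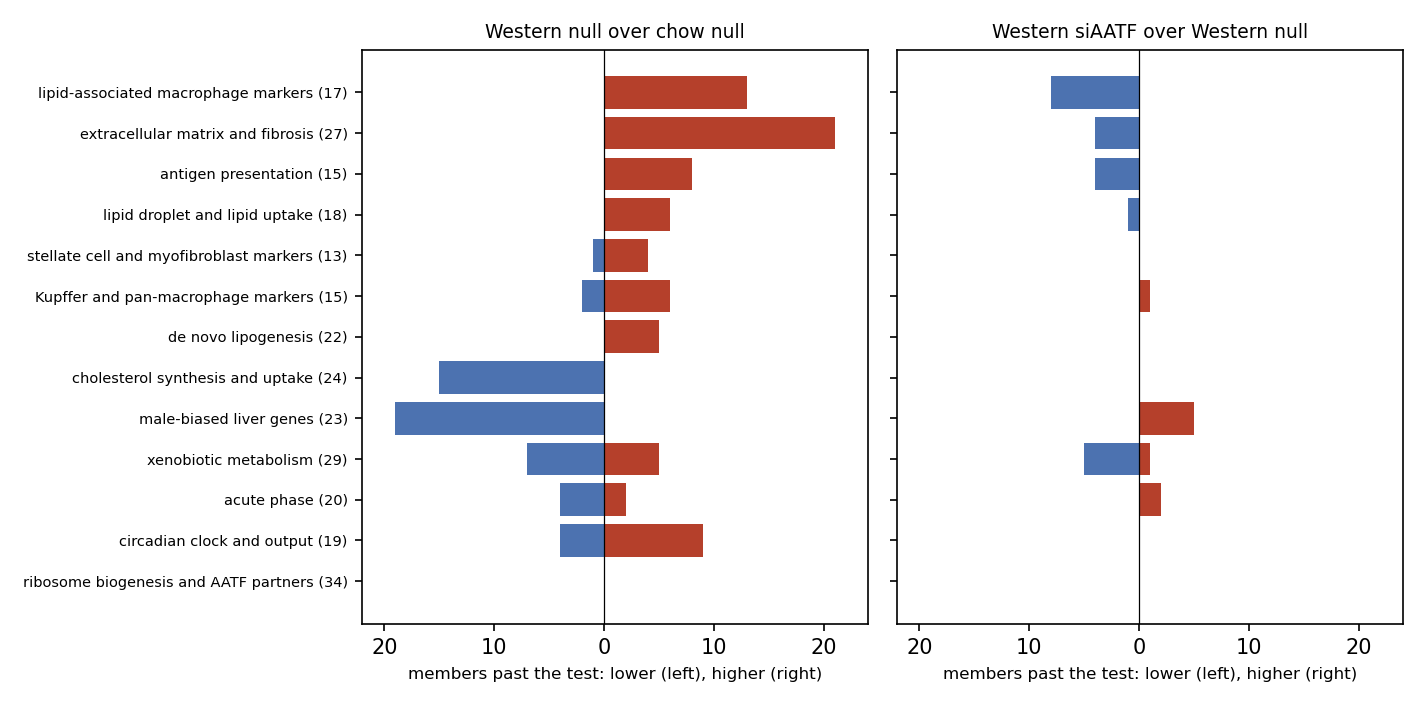
Number of list members past the edgeR test (x axis, lower to the left and higher to the right) for 13 of the fixed gene lists (y axis, measured members in parentheses), for the diet comparison (left panel) and for Western siAATF over Western null (right panel). Matrix genes were higher in 21 of 27 cases on the diet and lower in 4 of 27 in the Western siAATF libraries.

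The second comparison asks what the silencing vector did to the liver on the Western diet; its direction rests on the label, since Aatf was not lower in the libraries labelled siAATF. In those libraries 8 of 17 lipid-associated macrophage markers, 4 of 27 matrix genes and the class II genes H2-Aa, H2-Ab1, H2-Eb1 and Cd74 were lower, and 5 of 23 male-biased liver genes were higher. Most matrix genes, Col1a1 among them, did not pass. Gpnmb stood at 0.669 ± 0.222 CPM against 47.6 ± 4.49 in Western null (log2 fold change -6.04 ± 0.50; edgeR quasi-likelihood test, Benjamini-Hochberg adjusted p = 8.39e-06). Hsd3b5 stood at 62.4 ± 27.9 against 0.718 ± 0.883 CPM (6.54 ± 0.55; same test, adjusted p = 8.39e-06). Of 11934 genes, 37 were higher and 67 lower. With no low-count filter the excess turned, and 67.3% of 572 called genes were higher. For Gpnmb and Hsd3b5 all 3 Western siAATF libraries lay apart from all 3 Western null libraries, which the naming rule requires of genes named for the largest changes.

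Of 17 lipid-associated macrophage markers, 8 fell and 0 rose; adjusted over the list alone, 14 fell and 1 rose. Besides Gpnmb, Mmp12 fell by 4.49 ± 0.55, Trem2 by 2.84 ± 0.50, Spp1 by 2.64 ± 0.45, Cd63 by 2.05 ± 0.29 and Anxa5 was lower too (-1.82 ± 0.25). The list's camera call (adjusted p = 3.41e-16) held with an estimated correlation (adjusted p = 0.00156 with an estimated correlation). Of 27 matrix genes, 4 fell and 0 rose (16 and 0 adjusted over the list alone): Mmp12, Col6a3 (-1.81 ± 0.34), Bgn (-1.49 ± 0.25) and Fbn1 (-1.28 ± 0.26). Col1a1 did not pass (-2.17 ± 0.77), with 48.7, 11.6 and 123 CPM in the Western siAATF libraries against 200 to 350 in Western null, and the matrix list's call (adjusted p = 1.37e-17) was not kept with an estimated correlation (adjusted p = 0.0884 with an estimated correlation). The class II genes H2-Aa (-2.21 ± 0.38), Cd74 (-1.93 ± 0.39), H2-Ab1 (-1.86 ± 0.39) and H2-Eb1 (-1.85 ± 0.32) were the 4 of 15 antigen presentation genes that fell (5 adjusted over the list alone; adjusted p = 0.288 with an estimated correlation). Of 15 Kupffer and pan-macrophage markers, only Cd163 passed, and it rose (2.52 ± 0.57; 2 higher and 0 lower adjusted over the list alone); 37.0% of its span overlaps another gene. Other lists moved with these by camera. Stellate cell and cholangiocyte markers were called lower with 0 members past edgeR's test over all genes (1 higher and 2 lower, and 0 higher and 2 lower, adjusted over the list alone; adjusted p = 0.295 and 0.288 with an estimated correlation). The lysosome list was called lower with 0 members past edgeR's test, over all genes or adjusted over the list alone (adjusted p = 0.230 with an estimated correlation). Of 24 hepatocyte secreted proteins 1 rose, Serpina1c (1.25 ± 0.25), whose near-identical copies make the counts uncertain (5 higher adjusted over the list alone; adjusted p = 0.418 with an estimated correlation).

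Of 23 male-biased genes, 5 rose and 0 fell (13 and 0 adjusted over the list alone; adjusted p = 0.136 with an estimated correlation): besides Hsd3b5 they included Cyp7b1 (2.58 ± 0.50), Nudt7 (1.54 ± 0.26) and Serpina1e (4.81 ± 0.78). Serpina1e stood at 1514 and 1465 CPM in Western siAATF replicates 1 and 2 and at 93.8 in replicate 3, against 33.1 to 43.0 in Western null, and its call was lost without Western siAATF replicate 2 (adjusted p = 0.0673 by edgeR's quasi-likelihood test with Benjamini-Hochberg, log2 4.47), without each of the Western null replicates 1, 2 and 3 (4.92, 4.73 and 4.76), in a fit of the compared groups alone (4.82) and without the libraries with over 25% 18S RNA (4.47). Among 29 xenobiotic genes, 1 rose and 5 fell (2 and 10 adjusted over the list alone; adjusted p = 0.227 with an estimated correlation). The glutathione S-transferase genes Gstm3 (51.3 ± 15.2 to 2.09 ± 1.40 CPM, -4.51 ± 0.44), Gsta4 (-2.15 ± 0.37) and Gstm1 (-1.85 ± 0.33) were among those that fell. Gsta1 had 82 counts in Western null and 0 in Western siAATF, at least 19-fold lower. Cell cycle genes had 1 of 16 lower, Ccnd1 for cyclin D1 (-1.57 ± 0.26; 2 lower adjusted over the list alone), and the list's call held with an estimated correlation (adjusted p = 0.0491 with an estimated correlation). Of 26 p53 targets 1 fell, Cdkn1a (-3.04 ± 0.64; 1 adjusted over the list alone; adjusted p = 0.0508 with an estimated correlation).

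Apoa4 fell by 2.62 ± 0.33, from 8474 ± 1699 to 1378 ± 409 CPM, and was the only 1 of 18 lipid droplet and uptake genes to pass (1 lower adjusted over the list alone; adjusted p = 0.288 with an estimated correlation). Cd36 (-0.67 ± 0.48) and Cidec (-1.56 ± 0.93) did not pass, nor did Scd1 (-0.84 ± 0.37), Fasn (0.05 ± 0.38), Srebf1 (0.75 ± 0.35), Cyp7a1 (-0.18 ± 0.36), Fgf21 (-1.59 ± 1.06), Ddit3 (0.37 ± 0.41) or Cyp2e1 (0.01 ± 0.25). In Western siAATF replicate 3 Cd36 lay above all Western null libraries, and Cidec lay far above replicates 1 and 2. The values of these 2 genes thus depend on that library, and they do not show that lipid genes were unchanged. Without it the comparison called 413 genes in place of 104. The lists of de novo lipogenesis and of cholesterol synthesis had 0 members past edgeR's test, over all genes or adjusted over the list alone. By camera the cholesterol list was called higher, opposite to its fall on the diet (median log2 fold change 0.51, camera adjusted p = 0.00719). That call was not kept with an estimated correlation (adjusted p = 0.528 with an estimated correlation). The acute phase genes Itih3 (1.72 ± 0.37) and Fga (1.44 ± 0.32) rose (2 of 20; 12 adjusted over the list alone; adjusted p = 0.328 with an estimated correlation). Western siAATF replicate 3 stood apart here: Itih3 was at 2741, 3216 and 799 CPM and Fga at 8464, 8108 and 3696 CPM in replicates 1, 2 and 3. Saa1, named outside the rule after its values were seen, was at 8506, 5138 and 61.2 CPM and did not pass (4.46 ± 1.40). Both calls were lost without Western siAATF replicate 1 (1.56 for Itih3, 1.25 for Fga) or replicate 2 (1.38 and 1.28), without chow null replicate 3 (1.71 and 1.43) and without each chow siAATF or Western null replicate. They were also lost in the compared groups alone and without the libraries with over 25% 18S RNA. Of 34 genes of ribosome biogenesis and AATF partners, 0 passed edgeR's test in any of the 5 comparisons, over all genes or adjusted over the list alone. Other large changes were Ephb2, an ephrin receptor (34.6 ± 10.3 to 0.894 ± 0.393 CPM, -5.12 ± 0.53), Olig1 (-3.46 ± 0.77), Grm8, a glutamate receptor gene (1.08 ± 0.588 to 11.8 ± 2.32 CPM, 3.73 ± 0.52), Enho (4.08 ± 0.72), Prtn3 (6.39 ± 1.15, with 44.2, 25.9 and 1.76 CPM in the Western siAATF libraries), and Crybb3, with 59 counts against 2 (ratio 42.4, 11.2 to 358).

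Of 39 named genes called in this comparison, 11 stayed called in every alternative in which they were tested, with glmTreat and the adjusted p under 0.1 left out: Gpnmb, Mmp12, Cd63, Anxa5, H2-Aa, H2-Eb1, Ephb2, Gstm3, Apoa4, Hsd3b5 and Grm8. The count of 104 changed to 26, 47 and 28 without Western null replicates 1, 2 and 3, to 43, 67 and 413 without Western siAATF replicates 1, 2 and 3, and to 53 when only the compared groups were fitted.

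**Figure D3:**
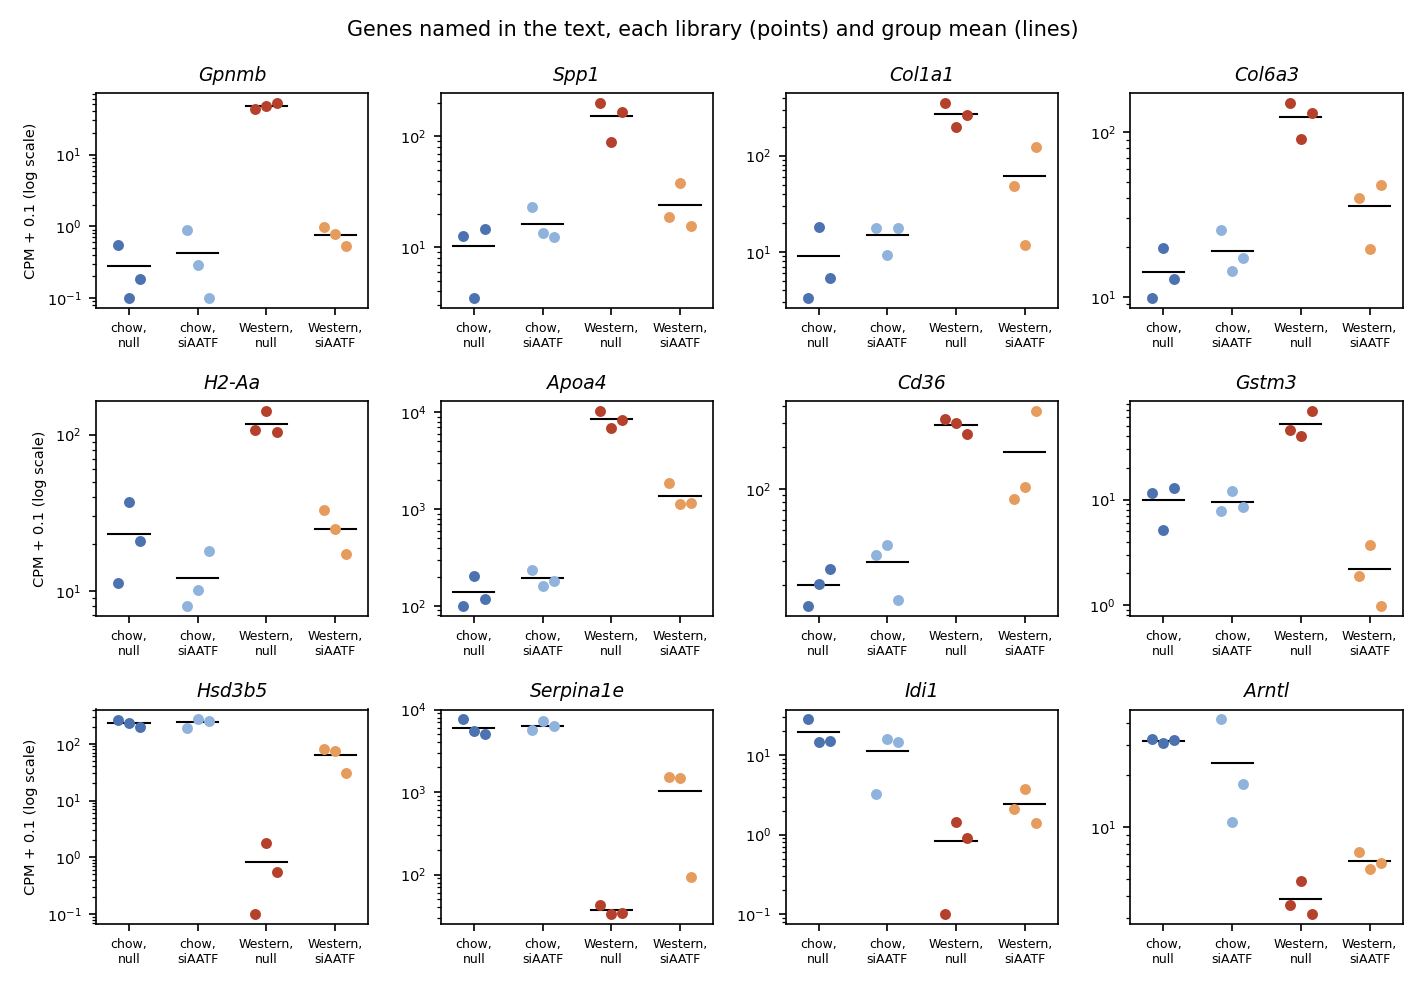
Level of 12 named genes in each library (points, CPM plus 0.1 on a log axis) with the group means (lines), for the 4 groups on the x axis. Gpnmb and Gstm3 in the Western siAATF libraries lie far under the Western null libraries, while Cd36 in Western siAATF replicate 3, at 366 CPM, lies above all 3 Western null libraries.

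The direction of the diet's genes was then followed from the first comparison into the second. Of the 1577 genes that the diet changed, 1452 (92.1%) had a fold change of the opposite sign in Western siAATF against Western null, and the median change went back by 42.2% of the diet's log2 fold change, against 9.13% on average (7.70% to 10.6%) in simulated data sets in which the vector changed nothing. Of the genes past the threshold in both comparisons, 59 rose on the diet and were lower in Western siAATF, and 32 fell on the diet and were higher; independent lists would share 4.32 and 2.51. There were 0 genes past edgeR's threshold in the same direction in both comparisons, where independent lists would share 2.38 higher and 4.54 lower. Both comparisons use the Western null libraries, which alone gives opposite signs: in 100 simulated data sets in which the vector changed nothing, 64.4% of diet genes had the opposite sign on average (62.3% to 66.7%). Across all genes Pearson's r was -0.621 against -0.200 simulated, and the covariance was -0.429 against -0.105 simulated; genes are not independent replicates. The simulated sets called 2496 diet genes on average and so held less spread than the data. In them each gene was drawn on its own, so variation that moves many genes of a library together is missing. Part of the excess may therefore come from the shared libraries. With the diet effect from 2 Western null libraries and the vector effect from the third, which share none, 84.6%, 91.3% and 86.1% of diet genes had the opposite sign.

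**Figure D4:**
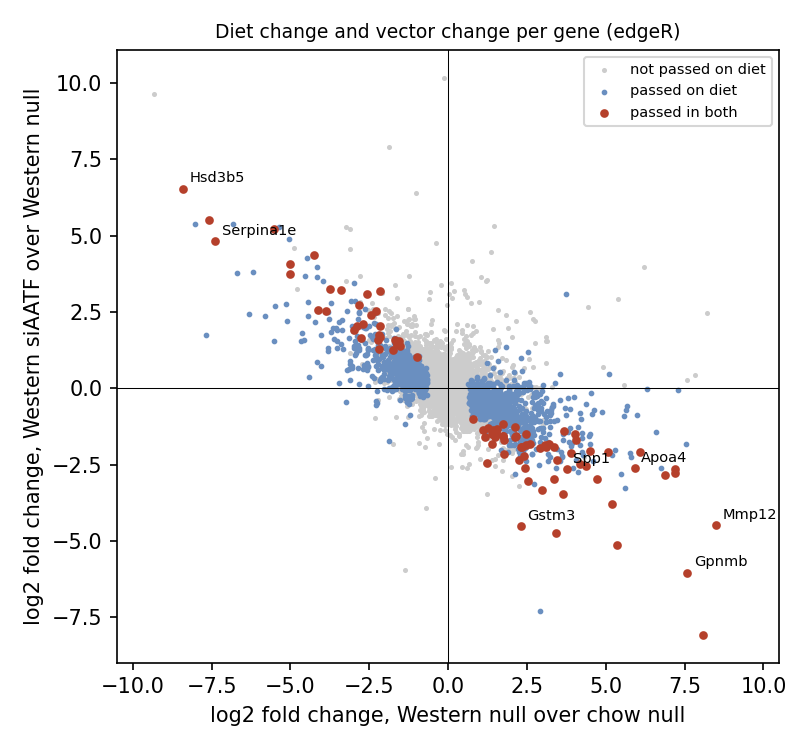
Log2 fold change of each tested gene for the diet (x axis, Western null over chow null) and for the vector label on the Western diet (y axis, Western siAATF over Western null), both from edgeR; red points passed in both comparisons. All 91 red points lie on the 2 sides where the signs differ, 32 above and 59 under 0 on the y axis.

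The third comparison asks what the vector did on chow. No gene group moved past the test for single genes: edgeR's quasi-likelihood test called 0 of 11934 genes, with 285 at an unadjusted p under 0.05, DESeq2 called 1 and limma-voom with quality weights called 1. Gpnmb (0.13 ± 0.88), Spp1 (0.54 ± 0.45), Col1a1 (0.99 ± 0.85), Cd36 (0.55 ± 0.50) and Scd1 (0.10 ± 0.37) did not pass. The genes with the smallest unadjusted p, none of which passed, were higher for Igfbp5, an insulin-like growth factor binding protein (2.22 ± 0.545 to 12.9 ± 4.65 CPM, 2.56 ± 0.51), Hspb1 (1.17 ± 0.33), Imp3 (0.78 ± 0.23), Col5a2 (1.51 ± 0.46) and Fbxw9 (0.82 ± 0.26). They were lower for Fmn1 (-0.98 ± 0.27), Rad51b (-1.78 ± 0.50), Slc37a1 (-1.83 ± 0.56), the metallothionein gene Mt2 (-4.56 ± 1.31) and Slc9a7 (-1.38 ± 0.44). By camera 1 list, oxidative phosphorylation, was higher and 4 were lower, of which the inflammatory cytokine list had the smallest adjusted p (0.000832; adjusted p = 0.227 with an estimated correlation). None of the 5 calls was kept with an estimated correlation or by fry, and none of these lists had a member past the test, over all genes or adjusted over the list alone. The fold changes of the vector on the 2 diets, which share no library, had a Pearson correlation of -0.155 and a Spearman correlation of -0.187 across genes, which are not independent replicates. Pearson's r turned to 0.00454 without chow null replicate 1, 0.0345 without Western siAATF replicate 2 and 0.0636 without the libraries with over 25% 18S RNA. The last value rests on chow null replicate 3 alone for its group.

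The diet's effect in mice given the silencing vector, and its difference from that with the null vector, follow from the 2 by 2 design. Western siAATF against chow siAATF had 91 genes higher and 86 lower. Apoa4 rose by 2.84 ± 0.33, Cd36 by 2.63 ± 0.51, Trem2 by 3.70 ± 0.74 and Cd63 by 2.38 ± 0.34, and Hsd3b5 fell by 1.92 ± 0.36, while Gpnmb (1.42 ± 0.79), Spp1 (0.60 ± 0.44) and Col1a1 (2.05 ± 0.79) did not pass. Of 17 lipid-associated macrophage markers 3 rose (6 adjusted over the list alone; adjusted p = 0.0101 with an estimated correlation), and of 27 matrix genes 0 passed edgeR's test over all genes (3 higher adjusted over the list alone; adjusted p = 0.288 with an estimated correlation). Diet fold changes with the 2 vectors had a Pearson correlation of 0.554, and 60 genes were higher and 55 lower in both, where independent lists would share 5.86 and 5.82. The count of 177 changed to 17 when only the compared groups were fitted, to 34 without chow siAATF replicate 2 and to 737 without Western siAATF replicate 3.

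The interaction of diet and vector passed for 23 genes, 12 with a more positive and 11 with a more negative change on the Western diet. Hsd3b5 had the smallest p, with an interaction of 6.48 ± 0.66 on the log2 scale (edgeR quasi-likelihood test, Benjamini-Hochberg adjusted p = 0.000278), followed by Gstm3 (-4.39 ± 0.56), Haus8, a subunit of the augmin complex of the spindle (-3.38 ± 0.46), Apoa4 (-3.08 ± 0.45) and Grm8 (3.87 ± 0.63). Of these 5 only Gstm3 stayed called in every alternative in which it was tested, with glmTreat and the adjusted p under 0.1 left out. Without chow null replicate 3 the calls of Haus8 (-3.21), Apoa4 and Grm8 (3.63) were lost, and that of Grm8 also without Western null replicate 1 (3.85) or 3 (3.19). Haus8 was lost after thinning (-2.81). The calls of Hsd3b5 (5.97) and Apoa4 (-3.06) were lost without the libraries with over 25% 18S RNA, which leaves only chow null replicate 3 in its group. Of the 17 lipid-associated macrophage markers 3 passed, all more negative (10 lower and 1 higher adjusted over the list alone; adjusted p = 0.00159 with an estimated correlation). The count fell to 2 without chow null replicate 3 and rose to 295 without Western siAATF replicate 3. Of 100 splits of the libraries within each diet, 5 gave at least 23 genes, the real one included, and all 5 kept the real Western grouping. The 88 splits that broke it gave at most 5 genes, but they also removed the vector difference on the Western diet itself. Of the 12 splits that kept it, 5 reached 23 genes and the highest gave 36. This division of the splits was chosen after the result was seen. A share of at least 0.05, as here, was set beforehand as within reach of regrouping, so the splits do not show that the vector's effect differed between diets.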

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

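The tests of the Aatf level, of the length correction and of the macrophage lists were chosen only after the result was seen; the simulation for shared libraries and the counts over splits were fixed before. These results were marked because a change differed between diets. The interaction count was 23 genes, and the interaction values were 6.48 for Hsd3b5, -4.39 for Gstm3, -3.38 for Haus8, -3.08 for Apoa4 and 3.87 for Grm8, each marked as past edgeR's quasi-likelihood test. The median interaction of the lipid-associated macrophage markers was -1.70. For the interaction, 5 of 100 splits gave at least 23 genes, and the highest other split gave 36. These 5 include the real split, and the other 4 kept the real Western grouping and regrouped only chow libraries, so they still hold the Western difference. The 88 splits that broke the Western grouping gave at most 5 genes, but they also removed that difference. This division of the splits was chosen after the result was seen. A share of at least 0.05, as here, was set beforehand as within reach of regrouping, so the splits do not show a difference between diets. For lists, 18 of 100 splits gave at least 14 called lists, and the highest other gave 20; of the 18, 12 kept the Western grouping and 6 did not.

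Aatf was not lower in the libraries labelled siAATF. Too few Aatf counts to see a halving is one explanation, but the lowest bound of the intervals was a log2 fold change of -0.47. Exchanged labels are another, and the largest ratio between any regrouping of the libraries within a diet was 1.41. No regrouping thus showed a halving, but exchanged labels with a weaker fall, or with a fall hidden by intron reads, would not be seen. Another is that reads from introns, over a span of 90.8 kb, could hide a fall of the spliced transcript. The counts do not separate introns from exons, so this cannot be told apart from a vector that left Aatf unchanged. The libraries were of liver tissue, while the promoter was directed to hepatocytes, so the Aatf level of hepatocytes alone was not measured.

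Most genes changed by the diet had the opposite sign in Western siAATF libraries against Western null. The shared Western null libraries could produce this alone. The real share was 92.1% against a simulated maximum of 66.7%, but each simulated gene was drawn on its own. Variation that moves many genes of a library together is thus missing, and the simulated range cannot decide this. With the diet effect from 2 Western null libraries and the vector effect from the third, which share none, the shares were 84.6%, 91.3% and 86.1%. The opposite signs were therefore also seen without a shared library. A trend with gene length could also produce calls, but after the length correction 93.3% of diet genes still had the opposite sign, and 108 genes were called, 97 of them among the 104. The real split of 3 against 3 called 104 genes and the highest other split 0, and splits of 3 against 3 are too few for a share under 0.05. Every other split also mixed the 2 groups, which moves their difference into the spread within groups. Its low count thus lends the real split no support. For lists the real split gave 21 and the highest other 15.

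Of 17 lipid-associated macrophage markers 8 fell in Western siAATF libraries without a matching fall of Kupffer and pan-macrophage markers. Fewer macrophages of all kinds could lower the lipid-associated markers. The mean log2 fold change was -1.63 for 17 lipid-associated markers and 0.38 for 15 Kupffer and pan-macrophage markers, and a permutation test exchanging genes between the lists gave a 2-sided p = 0.000990 for that difference. The medians were -1.49 and -0.31, and the same permutation test on the difference of medians gave p = 0.00112. On the diet the lipid-associated list had risen more, with a median of 2.58 against 1.05, and the other list held 6 higher and 2 lower genes. A partial return from the diet would thus also make the lists differ, so the test cannot tell whether macrophages were fewer. A change in the state of the remaining cells may account for the difference and was not tested here. Genes are not independent replicates, so these p-values describe the lists and not the animals.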

How the results depend on the processing

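The counts of changed genes depended on the method and the libraries used; the cause was not tested. The diet's 1577 genes became 3561 with limma-voom, 581 with glmTreat, 2420 at an adjusted p under 0.1, 785 among genes without an overlapping neighbour and 1031 without the libraries over 25% 18S RNA. Leaving out 1 library gave 658 to 2250. The 104 genes of the vector on the Western diet became 285 with DESeq2, 597 with limma-voom, 572 with no low-count filter, 53 in the compared groups alone, 43 with glmTreat and 157 at an adjusted p under 0.1, and 26 to 413 with 1 library left out. The 0 genes of edgeR's test on chow became 1 with DESeq2, 1 with limma-voom and 33 with no low-count filter. The 177 genes of the diet with the silencing vector became 513 with DESeq2, 1340 with limma-voom, 836 with no low-count filter, 17 in the compared groups alone, 38 with glmTreat, 408 at an adjusted p under 0.1, 93 after thinning and 103 without the libraries over 25% 18S RNA, and 34 to 737 with 1 library left out. The 23 interaction genes became 124 with DESeq2, 284 with limma-voom, 331 with no low-count filter, 6 with glmTreat, 51 at an adjusted p under 0.1, 14 among genes without an overlapping neighbour and 11 after thinning, and 2 to 295 with 1 library left out. Without the libraries over 25% 18S RNA, chow null keeps only replicate 3. The diet count given above for that omission therefore has no spread within chow null and cannot be weighed like the other counts. No interaction count is given for that omission.

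The 92.1% of diet genes with the opposite sign became 90.3% with no low-count filter and 93.4% after thinning, and 82.2% to 96.2% with 1 library left out. It became 83.1% without the libraries over 25% 18S RNA, where chow null replicate 3 stands alone in its group. The correlation of the vector's effects on the 2 diets, -0.155, became -0.0200 with no low-count filter, -0.121 with the stricter filter and -0.0860 after thinning. It turned to 0.00454 without chow null replicate 1, 0.0345 without Western siAATF replicate 2 and 0.0636 without the libraries over 25% 18S RNA, in a range of -0.224 to 0.0345 with 1 library left out. The log2 fold change of Aatf on the Western diet, 0.0600, turned to -0.0214 with limma-voom and -0.0615 after thinning, and ran from -0.0891 (without Western null replicate 2) to 0.189 with 1 library left out.

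The called lists, 24, 21, 5, 19 and 14 by camera, became 1, 2, 0, 1 and 1 with an estimated correlation and 18, 8, 0, 5 and 6 by fry. Of the lists called by camera with the preset correlation, 16, 8, 0, 5 and 6 were also called by fry. On chow, leaving out 1 library gave 3 to 11 lists. The signed -log10 p of fatty acid oxidation turned on the Western diet to 0.130 without Western siAATF replicate 1 and 0.0455 without replicate 2, in a range of -14.9 to 0.130 with 1 library left out. For the diet with the silencing vector it turned to -3.02 without replicate 3, in a range of -3.02 to 5.81.

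The labels do not state that equal replicate numbers pair the samples. Residual correlations between equal numbers ran from -0.150 to 0.259. They were not set against those of unequal numbers, so a shared batch is not excluded. With a replicate block the diet comparison called 1157 genes in place of 1577, the Western vector comparison 64, the diet with the silencing vector 71 and the interaction 14. The opposite-sign share was then 93.9% and the correlation -0.128.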

Other observations

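Western siAATF replicate 3 stood apart from replicates 1 and 2 in genes picked after their values were seen. The acute phase gene Saa1 stood at 8506, 5138 and 61.2 CPM in replicates 1, 2 and 3, the neutrophil gelatinase-associated Lcn2 at 684, 634 and 10.6, and the chemokine gene Cxcl1 at 18.4, 20.4 and 1.32. The droplet gene Cidec stood at 5.97, 12.3 and 131 CPM, and the cytochrome genes Cyp2b9 at 0, 0.227 and 328 and Cyp4a10 at 99.1, 172 and 3797. Without this library the Western vector comparison called 413 genes.

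Haus8 stood at 1.83 ± 0.433 CPM in chow null, 2.97 ± 0.740 in chow siAATF, 35.9 in Western null and 6.08 ± 1.44 in Western siAATF. The nuclear RNA Malat1, named outside the rule, stood at 2422 ± 604 CPM in chow null and 1151 ± 61.9 in Western null.

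Longer genes had lower fold changes in the diet comparison, with a Spearman correlation of -0.291 between gene span and log2 fold change; the test on nuclear RNA was chosen only after the result was seen. It was -0.323 for the vector on chow, which uses the same chow null libraries, so that part of a like sign could come from the sharing; no value without the sharing was computed. It was 0.117 for the vector on the Western diet, which shares the Western null libraries, -0.0871 for the diet with the silencing vector, which shares none, and 0.261 for the interaction. Overlapping neighbours could produce the trend, but it was -0.267 in the 6352 genes without one. Low counts could also produce it, but it was -0.406 in the 2424 genes above 50 CPM. As a hypothesis, a different share of nuclear, unspliced RNA between libraries could account for it. Malat1 correlated with the share of counts in spans over 100 kb across the 12 libraries (Pearson 0.736), and within groups the correlation was 0.606 (permutation p = 0.210), so that explanation and a change of transcription of long genes cannot be told apart.

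Other splits were also tried for the other comparisons. For the diet with the null vector the real split called 1577 genes and the highest other 0, and 24 lists against 15. For the vector on chow edgeR's real split called 0 genes and the highest other 0, so 10 of 10 splits had at least as many; it called 5 lists against 18, and 10 of 10 splits had at least as many. For the diet with the silencing vector the real split called 177 genes and the highest other 8, and 19 lists against 15. Splits of 3 against 3 are too few for a share under 0.05.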
